A study of Danio rerio with 72 samples.

How the data were processed

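Gene expression was measured by polyA RNA-seq (single-end reads, stranded) in pools of 8 whole zebrafish embryos of the Tropical 5D line at 48 h after fertilisation, per the labels. Embryos had been exposed from gastrula stages to 1 of 16 PAHs or to DMSO alone at 1%, per the labels' protocols. The 72 samples formed 18 groups of 4, taken from the labels. The labels do not say that the pools of a group came from separate exposures, so p-values measure the spread between pools, part of which may be technical.

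The deposited table held 1 log2-scale value per gene and sample for 23175 genes, all 72 columns matched to samples by name. The submitters' processing notes name Trimmomatic, FastQC, Salmon, MultiQC and DESeq2, without versions, and the genome build Zv9. The deposited log2 values had the form of a variance-stabilizing transformation, with 1 common lowest value in every column. Undoing it gave normalized counts that were whole multiples of 1 step per sample for 100% of values, within 0.01 of a read, so whole reads and size factors (0.717 to 1.84) were recovered. Depth was 17584690 to 44103455 reads per library, and intervals cover the spread between libraries. The transformation compresses differences of weakly expressed genes, so a log2 difference understates their change; normalized counts are given for part of the genes and for the others the log2 difference alone. Symbols came from a table of gene identifiers and names that matched 20964 identifiers; many are in human style, and CYP1A1 stands for zebrafish cyp1a. Where 2 genes shared a symbol the identifier is given. Reads shared between zebrafish paralogs could be divided between them by the authors' counting, which makes values of close paralogs less certain. No coordinates are printed, since no annotation of Zv9 was used here.

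Tests ran in R 4.3.3 with limma 3.58.1, with tables and figures from Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Before the data were examined, the groups, gene lists, tests, alternatives and the rule for named genes were fixed. A single limma model with 18 group means was fitted to the deposited values of the 22634 genes with a normalized count of at least 10 in at least 4 samples, with trended and robust variance moderation. For each compound, a gene took the larger of its p-values against DMSO_1 and DMSO_2, or 1 where the signs differed, and these were adjusted by the Benjamini-Hochberg method at 0.05. The 5 pairs of related compounds at 50 µM took the largest p of the difference itself and of that difference plus or minus the difference between the DMSO sets. The design had assumed count-like values; the filter of 10 and the minimum mean of 50 for named genes were therefore applied to normalized counts, and count tests planned for raw counts were replaced by limma's voom on the recovered reads. Named genes were every tested member of the AHR list, the 8 largest increases and decreases among called genes with a mean of at least 50 and all 4 samples on one side of both DMSO means, and up to 4 called members of each other list, with 5 in each direction for pairs and for the DMSO sets. The text takes the largest changes and list members in rank order; AHR members are given as counts with some picked out after their values were seen, which departs from the rank order fixed beforehand. CYP1A1 is given for pairs as well, which the rule did not name and which was decided after its values were seen.

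The 20 fixed lists covered the AHR battery, NRF2 and oxidative stress, the unfolded protein response, heat shock, p53 and DNA damage, the cell cycle, cholesterol synthesis, retinoid metabolism, the circadian clock, and markers of lens, photoreceptors, neurons, skin, cartilage, skeletal and cardiac muscle, endothelium, erythrocytes, immune cells, and liver and yolk. Of 446 listed names, 313 matched by symbol, 38 by synonym and 48 without the paralog letter. Lists were tested with camera at a preset correlation of 0.01 against both DMSO sets, taking the larger p, adjusted over all compounds and lists, and again with an estimated correlation.

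The tests were tried on simulated data with known answers. With 200 of 22634 genes changed in the retene group, the calls recovered 56.0% of genes changed 1.5-fold, 82.0% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, with 0 false calls. All changed genes had a DMSO mean of at least 50 normalized counts, so recovery of weaker genes was not measured. Genes were simulated independently, without deviations shared across a library, so the false calls may not carry over to the real data. The pair test, tried on 9-methylanthracene against anthracene, recovered fewer, 24.0% of genes changed 1.5-fold and 58.0% of those changed 2-fold, or 18.0% and 60.0% with genes shifted between the DMSO sets and the first compound grouped with DMSO_2. With 500 further genes shifted between DMSO sets, requiring both controls gave 0 false calls and using their mean gave 180. No pair of libraries within a group agreed within sampling noise: the squared difference per gene ranged from 7.72 to 124 times that of counting alone over 108 pairs. Alternatives were another pseudocount, no filter, quantile normalization, the replicate number as a block, leaving out each library, each DMSO set alone or their mean, and only the compound and DMSO; a pseudocount of 1, voom, and leaving out the 4 libraries whose root mean square deviation from their group exceeded 0.2 were added after seeing the data. Those libraries were acenaphthene replicate 4, anthracene replicate 3, dibenzo[a,h]pyrene replicate 2 and 3-nitrofluoranthene replicate 4.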

Results

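The data were 72 RNA-seq libraries from whole zebrafish embryos collected at 48 h after fertilisation, made to compare the transcripts that change with each of 16 polycyclic aromatic hydrocarbons (PAHs), combustion- and petroleum-derived compounds built of fused aromatic rings. Each compound was tested at 1 concentration in 1% DMSO, and 2 sets of embryos in DMSO alone (DMSO_1 and DMSO_2) were the controls. Every group held 4 libraries, each a pool of 8 embryos. The libraries held 17584690 to 44103455 reads counted in genes. The deepest library was DMSO_1 replicate 1. The study's design text says that samples were collected on 2 days, with DMSO on each. Nothing in the labels says which of the 2 DMSO sets was collected with which compounds. A gene was therefore called for a compound only where it differed from both sets in the same direction. Levels are normalized counts, as mean ± SD over 4 libraries per compound and 8 DMSO libraries, and differences are on the deposited log2 scale, ± SE, against the mean of both DMSO sets. All adjusted p-values for genes are from limma and those for gene lists from camera.

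The first comparison asked how far the DMSO sets themselves differed. Clock genes were lower in DMSO_2: nr1d2a, a nuclear receptor that represses clock transcription, stood at 1105 ± 89.3 against 2399 ± 745 in DMSO_1 (log2 difference -0.98 ± 0.15, adjusted p = 4.12e-05), and the period gene PER1 (ENSDARG00000012499) at 1354 ± 216 against 2664 ± 357 (-0.91 ± 0.10, adjusted p = 1.55e-08). The cryptochrome CRY1 (ENSDARG00000045768) fell by 0.72 on the log2 scale. FKBP5, a chaperone gene induced by glucocorticoids, fell to 75.5 ± 12.6 from 504 ± 255 normalized counts, and KLF9, another glucocorticoid-responsive gene, fell to 9.34 ± 3.2 from 50.7 ± 10.9. The clock list had 30 measured members, 0 up, 5 down and 25 not called (0 up and 13 down adjusted over the list alone); it was lower as a list (adjusted p = 7.62e-17, and adjusted p = 5.78e-05 with an estimated correlation). ARRDC3 (ENSDARG00000036028), E4F1 and DEDD2 rose. In all, 4 genes were higher and 17 lower of 22634 tested, and the count was 13 without DMSO_1 replicate 3, 11 without DMSO_1 replicate 4 and 40 without the 4 libraries that deviated most from their groups (acenaphthene replicate 4, anthracene replicate 3, dibenzo[a,h]pyrene replicate 2 and 3-nitrofluoranthene replicate 4, the 4 deviating libraries below). The erythrocyte, heat shock and cell cycle lists were higher in DMSO_2 and the lens and p53 lists lower, with adjusted p = 1.89e-05, 0.00113, 0.031, 3.20e-04 and 4.68e-04. With an estimated correlation these became adjusted p = 0.228, 0.228, 0.754, 0.583 and 0.228.

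CYP1A1 (ENSDARG00000098315), the monooxygenase gene that the aryl hydrocarbon receptor (AHR) switches on, was called with 9 of the 16 compounds, more than any other gene. From 277 ± 76.1 normalized counts in DMSO it reached 61049 ± 5193 with benzo[k]fluoranthene at 8.9 µM, 54486 ± 2969 with benzo[j]fluoranthene at 50 µM and 52997 ± 4739 with retene at 15.8 µM. It was 22269 ± 2853 with dibenzo[a,i]pyrene at 5 µM, 20775 ± 1785 with dibenzo[a,h]pyrene at 10 µM and 16446 ± 2155 with benzo[b]fluoranthene at 50 µM. Fluoranthene (2225 ± 357), 9-methylanthracene (1893 ± 337), both at 50 µM, and carbazole at 35.6 µM (1312 ± 117) raised it too. The concentrations differ between compounds, so the order of these levels is not an order of potency. With the other 7 compounds CYP1A1 was not called against both DMSO sets by limma over all genes, at 1756 ± 2239 with anthracene, 1074 ± 609.7 with phenanthrene, 1058 ± 282 with 3-nitrofluoranthene and 932 ± 288 with 4H-cyclopenta(def)phenanthren-4-one. Adjusted over the list alone it passed for these 4 (adjusted p = 0.00194, 0.00721, 0.0026 and 0.00593). The anthracene mean rested on replicate 4, at 5090.5 normalized counts, where the others held 316 to 980.2. The spread used for CYP1A1 was pooled over all 18 groups, so these uneven anthracene libraries widened it for every compound. The 3-nitrofluoranthene libraries held 703 to 1393 and those of 4H-cyclopenta(def)phenanthren-4-one 695 to 1349, where DMSO libraries held 197 to 394. A missing call therefore need not mean an unchanged CYP1A1. For 4H-cyclopenta(def)phenanthren-4-one (adjusted p = 0.087, and 0.0412 to 0.124 over its 5 alternatives) CYP1A1 was called with a pseudocount of 8.

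**Figure D1:**
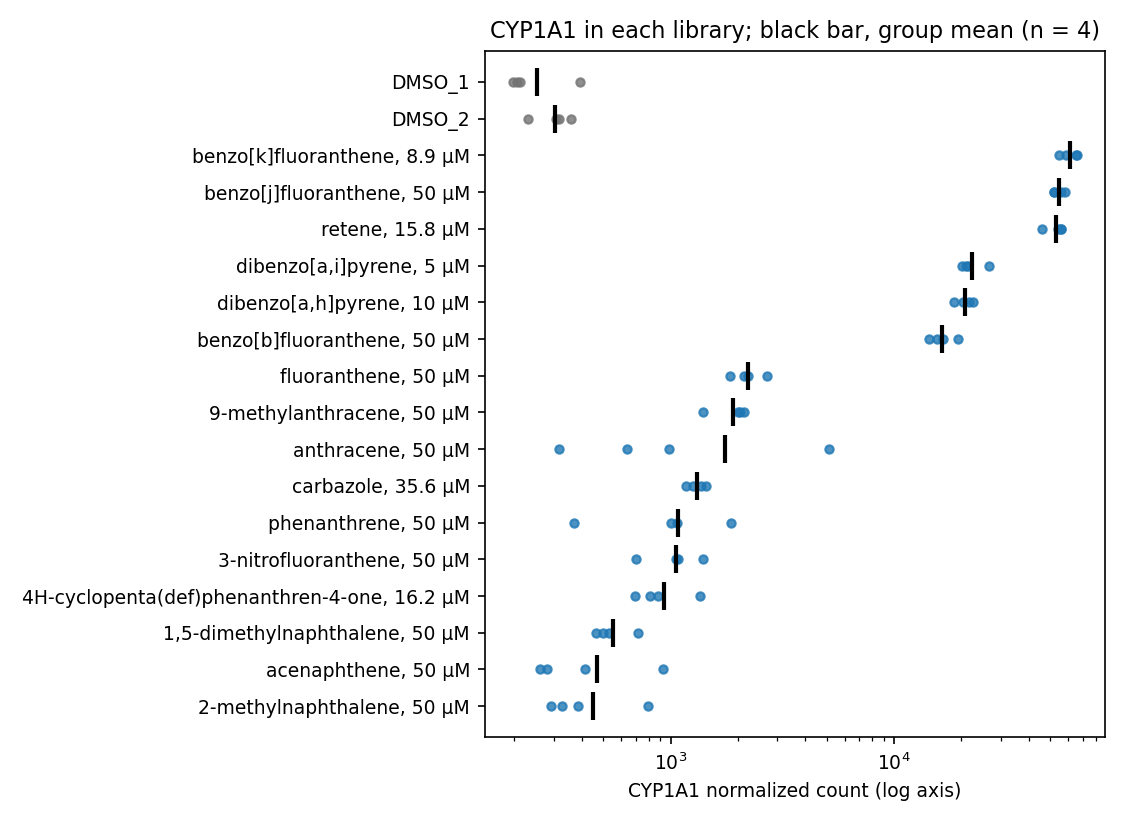
CYP1A1 level in each library, as normalized counts on a log axis, by group; dots are libraries, black bars group means of 4 libraries, and DMSO sets are grey. The benzo[k]fluoranthene, benzo[j]fluoranthene and retene means lie at 61049, 54486 and 52997, and those of the DMSO sets at 252 and 302.

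Retene raised genes of the AHR battery. The cytochrome genes cyp1c1 (9083 ± 839 against 228 ± 24.1 normalized counts, 39.8-fold), cyp1c2 (2194 ± 62.3 against 214 ± 34.0) and CYP1B1 (2150.4 ± 225 against 352 ± 33.9) rose. So did the AHR repressor genes ahrra (198 ± 56.6 against 5.06 ± 3.21) and ahrrb, the receptor gene ahr2 (0.71 ± 0.08 on the log2 scale) and tiparp. As a list, AHR genes were higher (adjusted p = 4.05e-77, and adjusted p = 2.27e-20 with an estimated correlation). The list had 21 measured members, of which 12 rose, 0 fell and 9 were not called, with 14 up and 0 down adjusted over the list alone. Among antioxidant genes prdx1 (ENSDARG00000058734), a peroxiredoxin, rose to 4332 ± 582 against 1788 ± 289.7, and GSR, glutathione reductase, to 1063 ± 108 against 448 ± 55.4. For the NRF2 list the test gave higher values (adjusted p = 8.70e-17, and adjusted p = 6.48e-07 with an estimated correlation). Among 16 measured members 7 rose, 0 fell and 9 were not called, with 8 up and 0 down adjusted over the list alone. The glutathione transferase gene gstp1.2 reached 23525 ± 1215 against 4907 ± 571 and the sulfotransferase gene sult6b1 2864 ± 254 against 557 ± 68.7. Genes that fell included the myoglobin gene mb (162 ± 30.0 against 337 ± 35.4), the keratin gene krt91 (7822 ± 415 against 11688 ± 613) and the dual oxidase gene duox (595 ± 176 against 1038 ± 111). The aggrecan gene acana (-0.47 ± 0.08) and STRA6, a vitamin A transporter (-0.45 ± 0.08), also fell. Skin genes as a list were lower (adjusted p = 0.00204, and adjusted p = 0.134 with an estimated correlation). Of 20 measured members, 0 rose, 1 fell and 19 were not called, with 0 up and 1 down adjusted over the list alone. The cholesterol list was lower (adjusted p = 1.11e-04, and adjusted p = 0.057 with an estimated correlation). The list had 21 measured members, of which 0 rose, 0 fell and 21 were not called, with 0 up and 1 down adjusted over the list alone. wfikkn1 (2.15 ± 0.09) also rose. si:dkey-65b12.6 (-0.69 ± 0.11) also fell. In all, 128 genes were higher and 24 lower. There were 203 higher and 142 lower genes against DMSO_1 alone, 207 higher and 77 lower against DMSO_2 alone and 265 higher and 145 lower against the mean of both.

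Benzo[k]fluoranthene at 8.9 µM raised CYP1A1 220.1-fold over the DMSO mean and cyp1c1 to 3826 ± 860.4 against 228 ± 24.1 normalized counts. CYP1B1 (3358 ± 648 against 352 ± 33.9), PKHD1L1 (ENSDARG00000091116, 3401 ± 583 against 258 ± 74.7) and the transcription factor gene FOXQ1 (1101 ± 168 against 151 ± 38.4) rose. CYB5A, cytochrome b5, rose to 7563 ± 898 against 2089 ± 307. As a list, AHR genes were higher (adjusted p = 4.65e-91, and adjusted p = 9.28e-22 with an estimated correlation). Among 21 measured members 12 rose, 0 fell and 9 were not called, with 13 up and 0 down adjusted over the list alone. The keratin genes krt4 (-0.61 ± 0.09 on the log2 scale), krt91 (-0.51 ± 0.10) and krt1-19e (12246 ± 950.1 against 22919 ± 1084) fell. The mucin gene muc5.1 (811 ± 55.0 against 1932 ± 226) and the ion cotransporter gene slc12a10.2 (249.6 ± 32.3 against 570.5 ± 55.3) fell too. For the skin list the test gave lower values (adjusted p = 2.55e-12, and adjusted p = 2.49e-04 with an estimated correlation). Of 20 measured members, 0 rose, 3 fell and 17 were not called, with 0 up and 6 down adjusted over the list alone. Endothelium genes as a list were higher (adjusted p = 3.71e-04, and adjusted p = 0.00323 with an estimated correlation). The list had 18 measured members, of which 0 rose, 0 fell and 18 were not called, with 0 up and 0 down adjusted over the list alone. The NRF2 list was higher (adjusted p = 0.0134, and adjusted p = 0.156 with an estimated correlation). Among 16 measured members 0 rose, 0 fell and 16 were not called, with 0 up and 0 down adjusted over the list alone. sult6b1 (2.21 ± 0.11) also rose. si:dkey-26g8.5 (-1.63 ± 0.29), ponzr3 (-1.12 ± 0.16), si:dkey-65b12.6 (-1.11 ± 0.11), duox (-0.98 ± 0.12) and ponzr4 (-0.98 ± 0.15) also fell. In total 74 genes were higher and 27 lower. There were 101 higher and 56 lower genes against DMSO_1 alone, 125 higher and 61 lower against DMSO_2 alone and 141 higher and 65 lower against the mean of both.

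Benzo[j]fluoranthene at 50 µM raised CYP1A1 196-fold. PKHD1L1 (ENSDARG00000091116) rose to 2419 ± 261 against 258 ± 74.7, sult6b1 to 3334 ± 186 against 557 ± 68.7, CYP1B1 to 2144 ± 119 against 352 ± 33.9 and gstp1.2 to 21073 ± 1245 against 4907 ± 571 normalized counts. As a list, AHR genes were higher (adjusted p = 3.25e-49, and adjusted p = 2.71e-16 with an estimated correlation). Of 21 measured members, 10 rose, 0 fell and 11 were not called, with 13 up and 0 down adjusted over the list alone. For the NRF2 list the test gave higher values (adjusted p = 4.82e-05, and adjusted p = 0.0127 with an estimated correlation). The list had 16 measured members, of which 1 rose, 0 fell and 15 were not called, with 7 up and 0 down adjusted over the list alone. The endothelial gene EGFL7 rose (0.42 ± 0.07 on the log2 scale). Endothelium genes as a list were higher (adjusted p = 1.11e-04, and adjusted p = 0.0013 with an estimated correlation). Among 18 measured members 1 rose, 0 fell and 17 were not called, with 2 up and 0 down adjusted over the list alone. The genes that fell included muc5.1 (952 ± 81.0 against 1932 ± 226), the fin-fold structural gene and2 (3248 ± 108 against 5792 ± 398), krt1-19e and slc12a10.2. RHBG, an ammonia transporter, fell (-0.65 ± 0.11, adjusted p = 0.0492, and 0.0328 to 0.0564 over its 5 alternatives), a call lost with no filter on low counts and voom. The skin list was lower (adjusted p = 0.0115, and adjusted p = 0.27 with an estimated correlation). Of 20 measured members, 0 rose, 1 fell and 19 were not called, with 0 up and 4 down adjusted over the list alone. cyp1c1 (2.77 ± 0.11) also rose. si:dkey-65b12.6 (-1.05 ± 0.11) also fell. In all 77 genes were higher and 12 lower, and 58 changed without benzo[j]fluoranthene replicate 4. There were 153 higher and 121 lower genes against DMSO_1 alone, 128 higher and 43 lower against DMSO_2 alone and 194 higher and 107 lower against the mean of both. Fitting only this compound and DMSO gave 105 higher and 33 lower.

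Benzo[b]fluoranthene at 50 µM raised CYP1A1 59.3-fold and cyp1c1 to 2079 ± 99.2 against 228 ± 24.1 normalized counts. DHRS13 (ENSDARG00000098746), a short-chain dehydrogenase gene, rose to 1125 ± 167 against 364 ± 60.4, gstp1.2 to 12261 ± 858 against 4907 ± 571 and PKHD1L1 (ENSDARG00000091116) to 792 ± 27.3 against 258 ± 74.7. As a list, AHR genes were higher (adjusted p = 2.72e-36, and adjusted p = 7.57e-14 with an estimated correlation). The list had 21 measured members, of which 9 rose, 0 fell and 12 were not called, with 12 up and 0 down adjusted over the list alone. For the NRF2 list the test gave higher values (adjusted p = 2.02e-05, and adjusted p = 0.0098 with an estimated correlation). Among 16 measured members 1 rose, 0 fell and 15 were not called, with 3 up and 0 down adjusted over the list alone. The clock gene PER2 rose (0.47 ± 0.08 on the log2 scale). SIK1, a salt-inducible kinase gene, fell to 496 ± 57.6 against 1027 ± 148. The potassium channel gene KCNQ2 (ENSDARG00000091130) fell to 113 ± 42.0 against 373 ± 71.9 (adjusted p = 0.0321, and 0.0129 to 0.0619 over its 5 alternatives), a call lost with a pseudocount of 8 and voom. sult6b1 also rose. si:dkey-65b12.6 (-0.88 ± 0.11) also fell. In total 29 genes were higher and 7 lower. There were 45 higher and 15 lower genes against DMSO_1 alone, 120 higher and 229 lower against DMSO_2 alone and 105 higher and 233 lower against the mean of both. Without the 4 deviating libraries there were 57 higher and 102 lower, and 51 higher and 94 lower when only this compound and DMSO were fitted, so the balance of increases and decreases turned in 4 of these 5 settings.

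Dibenzo[a,h]pyrene at 10 µM raised CYP1A1 74.9-fold, PKHD1L1 (ENSDARG00000091116) to 1126 ± 133 against 258 ± 74.7 and sult6b1 to 1743 ± 212 against 557 ± 68.7 normalized counts. The glucuronosyltransferase gene ugt1b1 rose to 1260.1 ± 114 against 635 ± 76.4. AHR genes as a list were higher (adjusted p = 1.51e-25, and adjusted p = 3.62e-11 with an estimated correlation). Of 21 measured members, 9 rose, 0 fell and 12 were not called, with 10 up and 0 down adjusted over the list alone. The genes that fell included SRGAP3 (249.7 ± 86.8 against 789.5 ± 94.2), the kinase gene MAP3K13 (224 ± 18.1 against 711 ± 119) and KCNQ2 (ENSDARG00000091130, 95.3 ± 23.4 against 373 ± 71.9). The myosin gene MYO5A fell to 346 ± 213 against 964 ± 176 (adjusted p = 0.0385, and 0.0198 to 0.0544 over its 5 alternatives), and the retinoic acid receptor gene RARG (ENSDARG00000054003) to 59.6 ± 28.1 against 293 ± 68.2 (adjusted p = 0.0155, and 0.0101 to 0.0644 over its 5 alternatives). Both calls were lost with voom. The 80 genes that fell had a median deviation of -0.81 on the log2 scale in acenaphthene replicate 4, a library that stood apart from its group. The collagen gene COL2A1 (ENSDARG00000011407) rose (0.49 ± 0.10, adjusted p = 0.0385, and 0.0352 to 0.0825 over its 5 alternatives), a call lost with quantile normalization. The keratin gene krt5 rose (0.38 ± 0.09, adjusted p = 0.0499, and 0.0466 to 0.088 over its 5 alternatives), a call lost with no filter on low counts, quantile normalization and voom. The NRF2 list was higher (adjusted p = 0.0391, and adjusted p = 0.272 with an estimated correlation). The list had 16 measured members, of which 0 rose, 0 fell and 16 were not called, with 1 up and 0 down adjusted over the list alone. As a list, skeletal muscle genes were higher (adjusted p = 0.0238, and adjusted p = 0.778 with an estimated correlation). Among 25 measured members 0 rose, 0 fell and 25 were not called, with 1 up and 0 down adjusted over the list alone. cyp1c1 (1.44 ± 0.11), DHRS13 (ENSDARG00000098746, 1.06 ± 0.12), CYP1B1 (1.02 ± 0.11) and wfikkn1 (0.99 ± 0.09) also rose. si:dkey-250d21.1 (-1.69 ± 0.27) also fell. prx fell (-1.40 ± 0.24, adjusted p = 0.045, and 0.00262 to 0.25 over its 5 alternatives), a call lost with voom. lifra fell (-1.39 ± 0.25, adjusted p = 0.0479, and 0.0247 to 0.106 over its 5 alternatives), a call lost with voom. In all 47 genes were higher and 80 lower. There were 197 higher and 270 lower genes against DMSO_1 alone, 322 higher and 451 lower against DMSO_2 alone and 519 higher and 625 lower against the mean of both. Without the 4 deviating libraries there were 42 higher and 365 lower, by voom 34 higher and 35 lower and with only this compound and DMSO 43 higher and 259 lower. The balance turned to increases without dibenzo[a,h]pyrene replicate 1 (92 higher and 65 lower), replicate 4 (78 higher and 54 lower) and replicate 5 (30 higher and 19 lower), and without DMSO_1 replicate 3 (27 higher and 20 lower). It also did with the score of each library on the axis of acenaphthene replicate 4 as a covariate (81 higher and 69 lower). The count was 68, 47, 82 and 55 without DMSO_1 replicates 1, 3, 4 and 5. It was 75 and 73 without DMSO_2 replicates 2 and 3, and 49 without dibenzo[a,h]pyrene replicate 5.

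Dibenzo[a,i]pyrene at 5 µM raised CYP1A1 80.3-fold, PKHD1L1 (ENSDARG00000091116) to 1416 ± 111 against 258 ± 74.7 and CYP1B1 to 1091 ± 97.6 against 352 ± 33.9 normalized counts. The transcription factor gene nfe2l2b rose to 294 ± 61.2 against 118 ± 25.5 and the clock gene PER2 to 220.2 ± 40.9 against 114 ± 15.0. For the AHR list the test gave higher values (adjusted p = 5.57e-38, and adjusted p = 3.77e-14 with an estimated correlation). Of 21 measured members, 8 rose, 0 fell and 13 were not called, with 11 up and 0 down adjusted over the list alone. The 3 genes that fell were SIK1 (533 ± 28.5 against 1027 ± 148), muc5.1 (1137 ± 199.8 against 1932 ± 226) and si:dkey-65b12.6 (4602 ± 481 against 7706 ± 932). Endothelium genes as a list were higher (adjusted p = 0.0259, and adjusted p = 0.0816 with an estimated correlation). The list had 18 measured members, of which 0 rose, 0 fell and 18 were not called, with 0 up and 0 down adjusted over the list alone. cyp1c1 (1.45 ± 0.11), sult6b1 (1.38 ± 0.11), DHRS13 (ENSDARG00000098746, 0.96 ± 0.12) and wfikkn1 (0.89 ± 0.09) also rose. In total 25 genes were higher and 3 lower. There were 74 higher and 31 lower against DMSO_2 alone and 59 higher and 17 lower against the mean of both DMSO sets.

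Fluoranthene at 50 µM raised CYP1A1 8.02-fold and lowered 3 of the 21 measured genes of cholesterol synthesis. The sterol regulator gene insig1 fell to 738 ± 89.4 against 1374 ± 89.6 normalized counts (-0.79 ± 0.08 on the log2 scale, adjusted p = 1.23e-07). HSD17B7 fell to 178 ± 9.75 against 313 ± 46.0 (adjusted p = 0.0469, and 0.0166 to 0.0636 over its 5 alternatives), a call lost with voom. LSS, lanosterol synthase, fell to 40.8 ± 7.38 against 93.6 ± 22.5 (adjusted p = 0.0469, and 0.0166 to 0.0884 over its 5 alternatives), a call lost with quantile normalization and voom. The cholesterol list was lower (adjusted p = 8.93e-18, and adjusted p = 5.92e-06 with an estimated correlation). Among 21 measured members 0 rose, 3 fell and 18 were not called, with 0 up and 9 down adjusted over the list alone. As a list, AHR genes were higher (adjusted p = 1.04e-07, and adjusted p = 1.80e-04 with an estimated correlation). Of 21 measured members, 1 rose, 0 fell and 20 were not called, with 5 up and 0 down adjusted over the list alone. The ABC transporter gene abch1 (449.8 ± 23.0 against 218 ± 29.9) and lonrf1 (708 ± 99.6 against 356 ± 115) rose, and SIK1 fell (548 ± 75.5 against 1027 ± 148). For the endothelium list the test gave higher values (adjusted p = 0.00234, and adjusted p = 0.0125 with an estimated correlation). The list had 18 measured members, of which 0 rose, 0 fell and 18 were not called, with 0 up and 0 down adjusted over the list alone. Immune genes as a list were higher (adjusted p = 0.00213, and adjusted p = 0.245 with an estimated correlation). Among 19 measured members 0 rose, 0 fell and 19 were not called, with 2 up and 0 down adjusted over the list alone. si:ch211-105c13.3 fell (-0.60 ± 0.11, adjusted p = 0.0469, and 0.0444 to 0.0617 over its 5 alternatives), a call lost with quantile normalization and voom. RGS2 fell (-0.50 ± 0.09, adjusted p = 0.0469, and 0.0444 to 0.0779 over its 5 alternatives), a call lost with quantile normalization and voom. In all 4 genes were higher and 6 lower, against 3 higher and 3 lower with quantile normalization, 3 higher and 2 lower by voom and 6 higher and 3 lower with only this compound and DMSO. With the replicate number as a block 4 were higher and 2 lower, so the block also ended calls among the decreases. There were 9 higher and 39 lower genes against DMSO_1 alone, 19 higher and 19 lower against DMSO_2 alone and 26 higher and 42 lower against the mean of both. The count was 5, with 3 higher and 2 lower, without any 1 of DMSO_1 replicates 3 and 4, DMSO_2 replicates 2, 3 and 4, and fluoranthene replicates 1 and 2. It was 6 without fluoranthene replicate 3 or 5.

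9-Methylanthracene at 50 µM gave the most calls of the 16 compounds when both DMSO sets were required. Against DMSO_2 alone dibenzo[a,h]pyrene had more (773 against 693), and concentrations differed between compounds. GNB3, a G protein subunit gene of the retina, fell to 152 ± 55.9 against 736 ± 118 normalized counts (-1.66 ± 0.17 on the log2 scale, adjusted p = 1.33e-07), and GNG13, another, to 354 ± 59.1 against 835 ± 84.0. The synaptic release gene STXBP1 (ENSDARG00000056036) fell to 341 ± 79.3 against 773 ± 62.7, and the neuronal transcription factor genes BHLHE23 to 274 ± 53.6 against 643 ± 76.6 and NEUROD6 (ENSDARG00000040008) to 106 ± 59.4 against 279 ± 36.4. The neural list was lower (adjusted p = 7.41e-05, and adjusted p = 0.0133 with an estimated correlation). Of 26 measured members, 0 rose, 4 fell and 22 were not called, with 0 up and 7 down adjusted over the list alone. The photoreceptor transcription factor gene crx (ENSDARG00000011989) fell (-0.62 ± 0.09). As a list, photoreceptor genes were lower (adjusted p = 0.0116, and adjusted p = 0.0946 with an estimated correlation). The list had 20 measured members, of which 0 rose, 1 fell and 19 were not called, with 0 up and 4 down adjusted over the list alone. Cell cycle genes rose, among them RRM1 (6150 ± 422 against 4587 ± 221) and the cyclin gene CCNA2 (2012 ± 118 against 1526 ± 43.7). For the cell cycle list the test gave higher values (adjusted p = 7.74e-19, and adjusted p = 0.00401 with an estimated correlation). Among 25 measured members 7 rose, 0 fell and 18 were not called, with 20 up and 0 down adjusted over the list alone. MCM2 (adjusted p = 0.047, and 0.046 to 0.0692 over its 5 alternatives) and MCM4 (adjusted p = 0.0488, and 0.0473 to 0.064 over its 5 alternatives) rose, and both calls were lost with quantile normalization and with voom. The cholesterol genes insig1 (-0.59 ± 0.08) and HMGCR (ENSDARG00000052734, -0.48 ± 0.10) fell. Cholesterol genes as a list were lower (adjusted p = 1.71e-06, and adjusted p = 0.0127 with an estimated correlation). Of 21 measured members, 0 rose, 4 fell and 17 were not called, with 0 up and 9 down adjusted over the list alone. The cartilage matrix genes MATN1 (13.9 ± 16.3 against 74.8 ± 9.4), COL9A1 and acana fell. The clock gene nr1d2a stood at 710 ± 81.6, where DMSO_1 held 2399 and DMSO_2 1105 (adjusted p = 0.0327, and 0.0231 to 0.054 over its 5 alternatives), a call lost with voom. It differed between the DMSO sets, so an effect of collection time cannot be told apart from the compound. The glutamate transporter gene SLC1A3 (ENSDARG00000104431, 3799.8 ± 1155 against 2025 ± 154) and the Notch target her15.1 (1109 ± 173 against 566 ± 126) rose. The AHR list was higher (adjusted p = 0.00662, and adjusted p = 0.0679 with an estimated correlation). The list had 21 measured members, of which 3 rose, 0 fell and 18 were not called, with 4 up and 1 down adjusted over the list alone. si:ch211-57n23.4 (1.11 ± 0.17) also rose. SQLE (ENSDARG00000079946, -0.54 ± 0.09), NEUROD1 (-0.55 ± 0.07), SNAP25 (ENSDARG00000058117, -0.42 ± 0.08) and ELAVL4 (-0.35 ± 0.07) also fell. In total 108 genes were higher and 206 lower. The count was 125 without 9-methylanthracene replicate 2 and 730 without the 4 deviating libraries. There were 540 higher and 845 lower genes against DMSO_1 alone, 283 higher and 410 lower against DMSO_2 alone and 665 higher and 924 lower against the mean of both.

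4H-cyclopenta(def)phenanthren-4-one, an oxygenated PAH, at 16.2 µM also lowered GNB3, to 201 ± 86.9 against 736 ± 118 normalized counts (-1.43 ± 0.17 on the log2 scale, adjusted p = 9.36e-06), GNG13 to 391 ± 72.6 against 835 ± 84.0, STXBP1 (ENSDARG00000056036) to 401 ± 67.7 against 773 ± 62.7 and prdm8a to 111 ± 34.9 against 247 ± 24.7. The neuronal transcription factor gene NEUROD1 fell (-0.44 ± 0.07). As a list, neural genes were lower (adjusted p = 0.0371, and adjusted p = 0.27 with an estimated correlation). Among 26 measured members 0 rose, 1 fell and 25 were not called, with 1 up and 2 down adjusted over the list alone. The photoreceptor genes crx (ENSDARG00000011989, -0.63 ± 0.09) and CRX (ENSDARG00000043483, -0.55 ± 0.08) fell, though their list was not called. For the cell cycle list the test gave higher values (adjusted p = 7.08e-15, and adjusted p = 0.013 with an estimated correlation). Of 25 measured members, 2 rose, 0 fell and 23 were not called, with 15 up and 0 down adjusted over the list alone. CCND1 (0.35 ± 0.07, adjusted p = 0.0247, and 0.0236 to 0.293 over its 5 alternatives) and mki67 (0.25 ± 0.05, adjusted p = 0.028, and 0.0219 to 0.465 over its 5 alternatives) rose, and both calls were lost with quantile normalization. The sodium pump genes atp1a1a.5 (253 ± 64.9 against 80.6 ± 19.6) and atp1a1a.2 (0.38 ± 0.07) and the ion cotransporter gene slc12a10.3 (103 ± 38.2 against 36.3 ± 11.5) rose. AHR genes as a list were higher (adjusted p = 0.00662, and adjusted p = 0.0679 with an estimated correlation). The list had 21 measured members, of which 0 rose, 0 fell and 21 were not called, with 3 up and 1 down adjusted over the list alone. The sterol regulator gene insig1 fell (-0.49 ± 0.08). The cholesterol list was lower (adjusted p = 4.42e-04, and adjusted p = 0.0893 with an estimated correlation). Among 21 measured members 0 rose, 1 fell and 20 were not called, with 0 up and 1 down adjusted over the list alone. As a list, lens genes were lower (adjusted p = 0.0219, and adjusted p = 0.885 with an estimated correlation). Of 25 measured members, 0 rose, 0 fell and 25 were not called, with 0 up and 0 down adjusted over the list alone. si:dkey-264f17.5 (0.87 ± 0.15) and abcb5 (0.65 ± 0.09) also rose. si:dkey-7c18.24 rose (0.74 ± 0.14, adjusted p = 0.0211, and 0.0167 to 0.0615 over its 5 alternatives), a call lost with voom. ly6pge (-0.75 ± 0.12) and igfn1.3 (-0.74 ± 0.13) also fell. In all 46 genes were higher and 70 lower. There were 237 higher and 381 lower genes against DMSO_1 alone, 136 higher and 154 lower against DMSO_2 alone and 343 higher and 388 lower against the mean of both. Without the 4 deviating libraries there were 129 higher and 127 lower, and with only this compound and DMSO 104 higher and 109 lower. The count was 61 and 56 without DMSO_1 replicates 3 and 4, and 76 without DMSO_2 replicate 4. It was 66 and 27 without 4H-cyclopenta(def)phenanthren-4-one replicates 1 and 4.

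Carbazole, a nitrogen-containing ring compound, at 35.6 µM lowered GNB3 to 220.1 ± 69.3 against 736 ± 118 normalized counts, GNG13 to 444 ± 60.4 against 835 ± 84.0 and STXBP1 (ENSDARG00000056036) to 421 ± 58.3 against 773 ± 62.7. For the photoreceptor list the test gave lower values (adjusted p = 0.00278, and adjusted p = 0.0487 with an estimated correlation). The list had 20 measured members, of which 0 rose, 2 fell and 18 were not called, with 0 up and 5 down adjusted over the list alone. SQLE (ENSDARG00000079946), squalene epoxidase, fell to 74.0 ± 10.5 against 209.8 ± 35.4, insig1 to 841 ± 48.0 against 1374 ± 89.6 and LSS to 37.8 ± 8.47 against 93.6 ± 22.5. Cholesterol genes as a list were lower (adjusted p = 2.05e-12, and adjusted p = 1.90e-04 with an estimated correlation). Among 21 measured members 0 rose, 6 fell and 15 were not called, with 1 up and 11 down adjusted over the list alone. The clock gene nr1d2a, at 623 ± 152, lay below DMSO_1 (2399) and DMSO_2 (1105). PER1 (ENSDARG00000012499), at 854 ± 69.8, also lay below DMSO_1 (2664) and DMSO_2 (1354). Both genes differed between the DMSO sets, and the labels give no collection time. An effect of collection time on clock genes cannot be told apart from carbazole here. The clock list was lower (adjusted p = 0.0158, and adjusted p = 0.395 with an estimated correlation). Of 30 measured members, 0 rose, 2 fell and 28 were not called, with 1 up and 3 down adjusted over the list alone. The genes that rose included the stress transcription factor gene ATF3, to 428 ± 227 against 180 ± 59.4, the heat shock protein gene dnajb1b to 1082 ± 729.8 against 493 ± 76.0 and ppp1r15a, a gene in none of the lists, to 1456 ± 503 against 854 ± 112. IGFBP1 rose to 484 ± 220.2 against 213 ± 71.9. As a list, heat shock genes were higher (adjusted p = 0.0352, and adjusted p = 0.482 with an estimated correlation). The list had 19 measured members, of which 1 rose, 0 fell and 18 were not called, with 5 up and 0 down adjusted over the list alone. For the unfolded protein list the test gave higher values (adjusted p = 3.07e-04, and adjusted p = 0.0893 with an estimated correlation). Among 18 measured members 1 rose, 0 fell and 17 were not called, with 5 up and 0 down adjusted over the list alone. NRF2 genes as a list were higher (adjusted p = 0.00556, and adjusted p = 0.105 with an estimated correlation). Of 16 measured members, 1 rose, 0 fell and 15 were not called, with 3 up and 0 down adjusted over the list alone. The cyclin gene CCND1 rose (adjusted p = 0.0279, and 0.0246 to 0.291 over its 5 alternatives), a call lost with quantile normalization. The cell cycle list was higher (adjusted p = 7.13e-09, and adjusted p = 0.0913 with an estimated correlation). The list had 25 measured members, of which 1 rose, 0 fell and 24 were not called, with 4 up and 0 down adjusted over the list alone. The cartilage genes COL9A1, acana and MATN1 fell; for MATN1 (adjusted p = 0.0389, and 0.0167 to 0.0813 over its 5 alternatives) the call was lost with voom. As a list, AHR genes were higher (adjusted p = 0.0248, and adjusted p = 0.128 with an estimated correlation). Among 21 measured members 2 rose, 0 fell and 19 were not called, with 4 up and 1 down adjusted over the list alone. For the immune list the test gave higher values (adjusted p = 0.0158, and adjusted p = 0.413 with an estimated correlation). Of 19 measured members, 0 rose, 0 fell and 19 were not called, with 3 up and 0 down adjusted over the list alone. Liver and yolk genes as a list were higher (adjusted p = 0.00244, and adjusted p = 0.371 with an estimated correlation). The list had 26 measured members, of which 0 rose, 0 fell and 26 were not called, with 5 up and 1 down adjusted over the list alone. EIF4EBP3 (ENSDARG00000041607, 0.66 ± 0.10) and zgc:153018 (0.65 ± 0.11) also rose. si:ch73-335l21.4 rose (0.70 ± 0.14, adjusted p = 0.0239, and 0.0196 to 0.116 over its 5 alternatives), a call lost with a pseudocount of 8 and voom. RDH10 (ENSDARG00000012369) rose (0.36 ± 0.07, adjusted p = 0.0389, and 0.0332 to 0.0548 over its 5 alternatives), a call lost with quantile normalization. igfn1.3 (-0.88 ± 0.13), prdm8a (-0.72 ± 0.10) and CRX (ENSDARG00000043483, -0.53 ± 0.08) also fell. In total 45 genes were higher and 70 lower. There were 257 higher and 339 lower genes against DMSO_1 alone, 144 higher and 143 lower against DMSO_2 alone and 367 higher and 344 lower against the mean of both. Without the 4 deviating libraries there were 113 higher and 138 lower. The count was 76 without DMSO_1 replicate 3, 73 without DMSO_2 replicate 4, and 45 and 60 without carbazole replicates 2 and 3.

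The other 6 compounds, all at 50 µM, gave 1 gene or none by limma. With 3-nitrofluoranthene the flow-responsive transcription factor gene klf2b rose (1124 ± 56.6 against 726 ± 107 normalized counts, adjusted p = 0.0302, and 0.0308 to 0.0505 over its 5 alternatives), with 2-methylnaphthalene the proneural gene ascl1b fell (337 ± 21.8 against 542 ± 43.8, adjusted p = 0.027), with phenanthrene SIK1 fell (514 ± 52.1 against 1027 ± 148, adjusted p = 5.95e-06), and with acenaphthene the spliceosome gene SNRNP40 rose (1270 ± 265 against 787 ± 73.1, adjusted p = 0.0142). No gene was called with anthracene or 1,5-dimethylnaphthalene by limma on the deposited values or by voom, where 1258 and 119 genes had an unadjusted p under 0.05. That p is the larger of the 2 against the DMSO sets, so chance alone is expected to give fewer such genes than a single test would. Against DMSO_1 alone these 6 compounds had 358 (3-nitrofluoranthene), 38 (2-methylnaphthalene), 2 (phenanthrene), 484 (acenaphthene), 400 (anthracene) and 16 (1,5-dimethylnaphthalene) genes, and against DMSO_2 alone 1, 2, 19, 93, 1 and 0. In the same order, the mean of both sets gave 101, 6, 4, 1088, 49 and 2. Without the 4 deviating libraries 3-nitrofluoranthene had 2 and acenaphthene 0, and acenaphthene had 0 when only it and DMSO were fitted. Fitting only 3-nitrofluoranthene and DMSO, 1 gene was called, which was not klf2b. With a pseudocount of 1 anthracene had 1. With the replicate number as a block the klf2b call was lost. It was also lost without any 1 of the 3-nitrofluoranthene libraries, DMSO_2 replicate 3 or DMSO_2 replicate 5, and without DMSO_2 replicate 2 the count was 2. The ascl1b call was lost without any 1 of the 2-methylnaphthalene libraries, DMSO_1 replicates 1, 4 or 5, or DMSO_2 replicates 3 or 4. The acenaphthene count was 0 without acenaphthene replicate 4, DMSO_1 replicates 4 or 5, or DMSO_2 replicates 3, 4 or 5, and 7 without acenaphthene replicate 3. The anthracene count was 1 without anthracene replicate 1 or 4, and phenanthrene kept a count of 1 in every case. Among lists, the clock list was lower with 3-nitrofluoranthene (adjusted p = 7.32e-04, and adjusted p = 0.154 with an estimated correlation). That list was also lower in DMSO_2 than in DMSO_1, so an effect of collection time cannot be told apart from 3-nitrofluoranthene. The AHR list was higher with 1,5-dimethylnaphthalene (adjusted p = 0.0115, and adjusted p = 0.0893 with an estimated correlation) and anthracene (adjusted p = 0.0158, and adjusted p = 0.104 with an estimated correlation). Of the anthracene libraries, replicate 4 held the highest CYP1A1, as given above, and the highest cyp1c1, at 603 normalized counts where the others held 246 to 279.8. The cell cycle list was higher with phenanthrene (adjusted p = 0.00398; adjusted p = 0.581 with an estimated correlation) and acenaphthene (adjusted p = 3.07e-04; adjusted p = 0.395 with an estimated correlation). Phenanthrene also had a lower cholesterol list (adjusted p = 6.00e-04; adjusted p = 0.0913 with an estimated correlation) and a higher endothelium list (adjusted p = 0.0448; adjusted p = 0.105 with an estimated correlation). Acenaphthene had higher lens, liver and yolk, and skeletal muscle lists (adjusted p = 0.0491, 0.0391 and 0.0115), which with an estimated correlation lay at adjusted p = 0.967, 0.653 and 0.673; acenaphthene replicate 4 stood apart from its group.

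**Figure D2:**
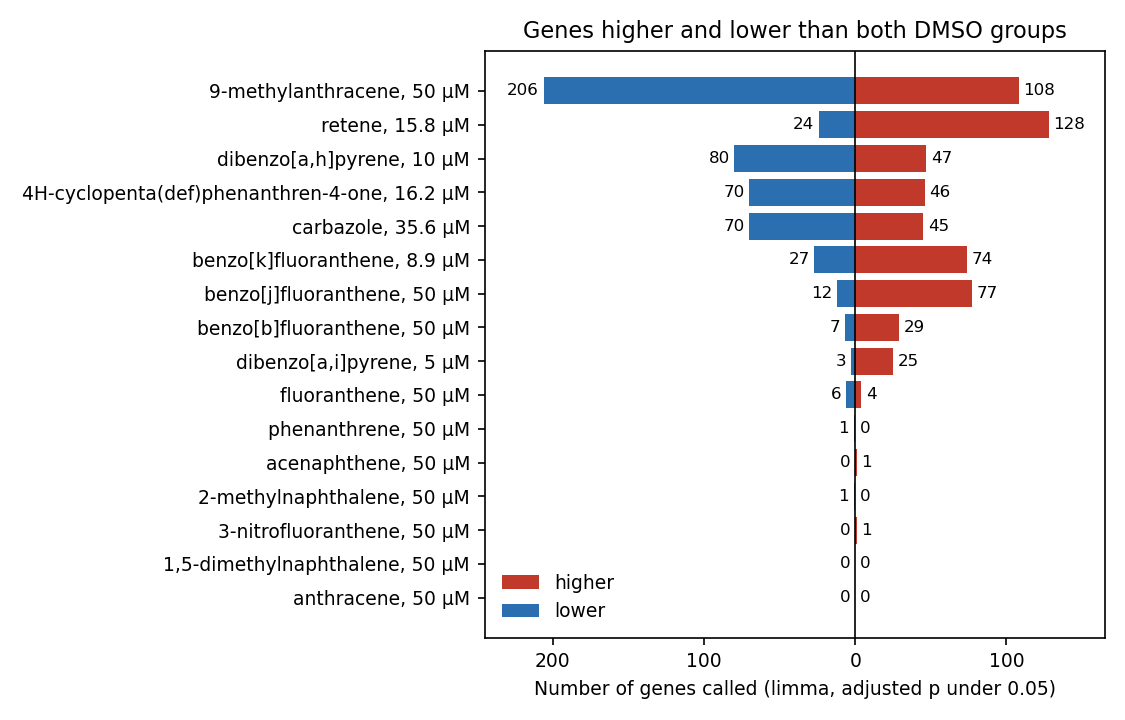
Number of genes higher (right) and lower (left) than both DMSO groups for each compound, limma adjusted p under 0.05, on a linear axis from 0. 9-Methylanthracene had 108 higher and 206 lower genes, and anthracene and 1,5-dimethylnaphthalene had 0.

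Over all compounds and lists, 53 of the 320 compound and list combinations were called with a preset correlation and 21 with an estimated one. The cardiac muscle, cartilage, erythrocyte, p53 and DNA damage, and retinoid lists were called with no compound; of the cartilage list acana fell with retene, carbazole and 9-methylanthracene, COL9A1 and MATN1 fell with the last 2 of these, and COL2A1 (ENSDARG00000011407) rose with dibenzo[a,h]pyrene. PLK3 of the p53 list rose with carbazole (0.35 ± 0.06 on the log2 scale) and 4H-cyclopenta(def)phenanthren-4-one (0.31 ± 0.06). In the retinoid list CYP26C1, a retinoic acid hydroxylase gene, rose with 9-methylanthracene (1258 ± 106 against 929 ± 39.4 normalized counts) and carbazole (1225 ± 44.0 against 929 ± 39.4), and RDH10 (ENSDARG00000012369) rose with carbazole. STRA6 of that list fell with retene and RARG (ENSDARG00000054003) with dibenzo[a,h]pyrene.

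**Figure D3:**
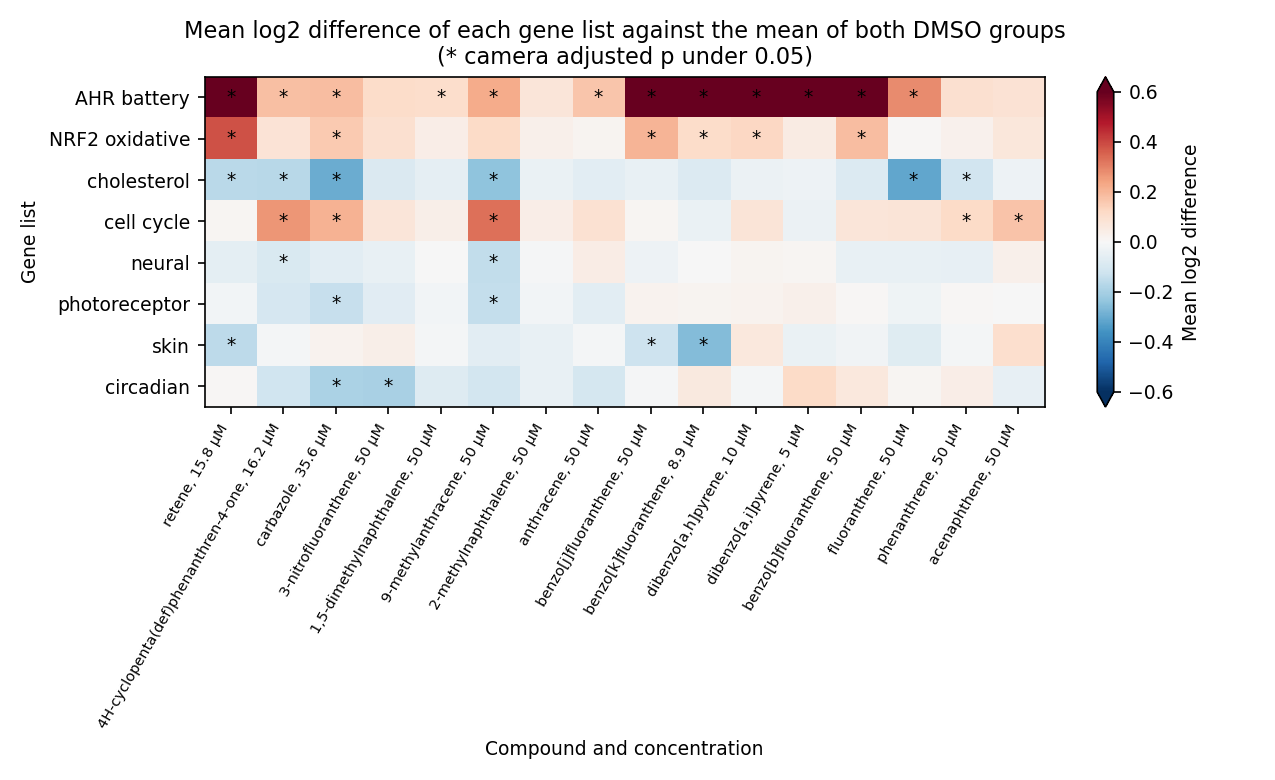
Mean log2 difference of 8 gene lists for each compound against the mean of both DMSO groups, as colour from blue (lower) to red (higher); stars mark camera adjusted p under 0.05 with a preset correlation, and the darkest AHR cells of 6 compounds lie beyond the colour scale. The AHR battery mean reached 1.35 with retene, and the cholesterol mean -0.31 with fluoranthene.

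Related compounds tested at the same 50 µM were compared directly, calling a gene only where the difference kept its sign and passed as it stood, with the difference between the DMSO sets added, and with it subtracted. In simulated data on genes averaging at least 50 in DMSO, this pair test recovered 24.0% changed 1.5-fold and 58.0% changed 2-fold. Low counts here therefore leave room for differences of that size. 9-Methylanthracene carries a methyl group on the middle ring of anthracene. Relative to anthracene it lowered GNB3 (152 ± 55.9 against 727 ± 221 normalized counts, -1.62 ± 0.19, adjusted p = 0.00227), GNG13 (-0.98 ± 0.12), the synaptotagmin gene syt5b (-0.95 ± 0.12) and myhb (-0.89 ± 0.12), and raised LRRN1 (18627 ± 1460.3 against 11235 ± 617) and epha2a (0.52 ± 0.08), with 3 genes higher and 16 lower. This count was 1082 without the allowance for the DMSO sets and 43 without the 4 deviating libraries, and 10, 11, 12, 11, 12 and 12 without DMSO_1 replicate 1, DMSO_1 replicate 5, DMSO_2 replicate 3, DMSO_2 replicate 5, 9-methylanthracene replicate 2 and anthracene replicate 5. ENSDARG00000102113 (0.97 ± 0.12) also rose. ccdc88aa (-0.94 ± 0.12) also fell. CYP1A1 was not called between this pair (0.75 ± 0.35, 95% interval 0.05 to 1.44).

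Benzo[b]fluoranthene and benzo[j]fluoranthene are isomers that differ in where the added benzene ring is fused. PKHD1L1 (ENSDARG00000091116) was lower with benzo[b]fluoranthene (792 ± 27.3 against 2419 ± 261 normalized counts, -1.45 ± 0.15, adjusted p = 6.47e-04, and 3.31e-04 to 0.0654 over its 5 alternatives), as was CYP1B1 (963 ± 36.6 against 2144 ± 119, adjusted p = 0.0158, and 0.00936 to 0.321 over its 5 alternatives). Neither was called with a pseudocount of 8 or of 1, and by voom CYP1B1 was not. CYP1A1 stood at 16446 ± 2155 against 54486 ± 2969, a difference of -1.73 ± 0.35 (95% interval -2.42 to -1.03). It was not called over all genes, though it passed adjusted over the list alone (adjusted p = 0.0126). The CYP1A1 libraries did not overlap, at 14378 to 19409 against 51945 to 57962. The SE of CYP1A1 was pooled over all 18 groups, the uneven anthracene libraries included. The count was 1 without DMSO_1 replicate 3 or 5, DMSO_2 replicate 2 or 3, benzo[j]fluoranthene replicate 1 or 5, or benzo[b]fluoranthene replicate 1, and 26 without the allowance for the DMSO sets. 3-Nitrofluoranthene, fluoranthene with a nitro group, differed from fluoranthene in abch1 alone (186 ± 17.8 against 449.8 ± 23.0, -0.89 ± 0.08, adjusted p = 8.34e-05), and CYP1A1 was not called (95% interval of the log2 difference -1.69 to -0.31). Without the allowance for the DMSO sets 91 genes were called. Phenanthrene and anthracene are isomers with an angular and a linear ring arrangement. They differed in SIK1 (514 ± 52.1 against 1223 ± 61.5, adjusted p = 0.00315), with 2 genes called without anthracene replicate 1 and 85 without the allowance for the DMSO sets. 1,5-Dimethylnaphthalene and 2-methylnaphthalene differed in 0 genes by limma and by voom, where 20 genes had an unadjusted p (the largest of each gene) under 0.05. The CYP1A1 difference was 0.30 ± 0.35 with a 95% interval of -0.39 to 0.99.

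Called genes overlapped between compounds. Of the genes lower with 9-methylanthracene, 53 were also lower with 4H-cyclopenta(def)phenanthren-4-one and 52 with carbazole, where independent lists would share 0.637 and 0.637. In simulated data without changes, DMSO libraries redrawn too, the same groups shared 0 and 0. Unchanged groups give few or no calls, so this cannot measure overlap made by the shared controls. The covariance of the log2 differences was 0.0136 and 0.0130, against 0.00309 and 0.00301 in the simulation. With split controls, 9-methylanthracene against DMSO_1 and the other against DMSO_2, the shared decreases were 92 and 93 (independent lists, 5.75 and 5.34). The increases shared by benzo[j]fluoranthene and benzo[k]fluoranthene numbered 46, and those shared by benzo[j]fluoranthene and retene 50, where independent lists would share 0.252 and 0.435. With split controls they were 62 and 69 (independent lists, 0.845 and 1.15).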

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

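The deviation threshold and library axis used below were chosen after the data were seen. The tests on slower development and on the clock limbs, and the size kept after thinning for dibenzo[a,h]pyrene, were chosen or changed after their results were seen.

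Single samples were compared with the other 3 of their group for 4 measures, 72 tests in all, and 10 values, from 9 samples, stood apart by Dixon's gap test, where chance gives about 1 in 20. Library totals, in M (mega) reads, stood apart in DMSO_1 replicate 1 at 44.1 where the others held 18.9 to 21.7, in 9-methylanthracene replicate 1 at 17.6 where the others held 22.2 to 22.8 and in fluoranthene replicate 1 at 33.6 where the others held 23.0 to 24.3. The share of reads in the 20 highest genes was 16.0% in 9-methylanthracene replicate 2 and 17.6% in dibenzo[a,h]pyrene replicate 2. The deposited log2 value of CYP1A1 was 9.06 where the others held 8.36 to 8.43 for DMSO_1 replicate 4, 15.49 where the others held 15.73 to 15.78 for retene replicate 3 and 10.59 where the others held 11.06 to 11.15 for 9-methylanthracene replicate 1. Scores on the first principal component were 4.32 for dibenzo[a,i]pyrene replicate 1 and 17.8 for acenaphthene replicate 4, whose other libraries lay from -2.29 to -0.342.

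The 80 genes lower with dibenzo[a,h]pyrene (median log2 difference -0.65) were also low in acenaphthene replicate 4, with a median deviation of -0.81. With each library's score on the axis of that library as a covariate, 77.1% of the median difference was left and 63 genes were still called. The axis was built from genes not called with dibenzo[a,h]pyrene. Libraries of this compound scored 0.066 to 0.146 on it, where acenaphthene replicate 4 scored 0.946. A covariate that rests largely on 1 library could remove only a part, so this does not decide whether the axis was the cause. The covariate also cut the median SE of these genes from 0.118 to 0.0930, so the calls kept rest partly on a smaller SE. Depth was tested by thinning to the lowest depth. Of the genes 70% were still called, within its SE of 5.12 of the 67% limit set beforehand, so that test did not decide. Of the median size 91.2% was left, a criterion added after the 70% was seen. Thinning leaves the expected size of a difference nearly unchanged, so that share does not decide either. Leaving out any 1 dibenzo[a,h]pyrene library left at least 95.9% of the median. These 80 genes were chosen with all 4 libraries, so their median could hardly fall and does not exclude a single library. Refits without replicates 1, 2, 4 and 5 called 65, 88, 54 and 19 genes lower. An effect of the compound stays open as a hypothesis, and reads shared between paralogs were not tested.

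With 9-methylanthracene, 4H-cyclopenta(def)phenanthren-4-one and carbazole the cell cycle list mean lay above the mean of the neural and photoreceptor lists by 0.48, 0.36 and 0.30 on the log2 scale. The library axis as a covariate left 94.8%, 95.7% and 90.9% of these, and thinning left 96.8%, 96.7% and 96.4%. Neither test could have removed much. Mean axis scores of these groups were 0.031, -0.0048 and 0.042, near DMSO_1 (-0.075) and DMSO_2 (-0.054), where acenaphthene replicate 4 scored 0.946. Thinning lowers precision and leaves the expected size of a difference nearly unchanged. These shares therefore decide neither cause. Slower development of the whole embryo could give the same pattern. It was assumed, without a stage reference, to lower the lens, cartilage, skeletal muscle, erythrocyte and cardiac muscle lists as well. With the 3 compounds in turn, 3, 3 and 2 of these 5 medians lay below 0. The criterion first compared the medians with the mean of both DMSO sets, and would have excluded this for 4H-cyclopenta(def)phenanthren-4-one and carbazole. It was then changed, after that result was seen, to require medians above 0 against both sets, under which slower development cannot be told apart from a direct effect with any of the 3 compounds.

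The clock genes lower in DMSO_2 may reflect collection at another point of the daily cycle, in which case genes of the opposite limb could be higher. The median log2 difference of the 5 bmal and clock genes was 0.0359, against -0.23 for the 14 period, cryptochrome and nr1d genes. A first criterion counted any median above 0 as support; it was changed after that result was seen to need more than the median SE of 0.115, and by it the data do not decide. After thinning, 100% of the called clock genes were called again, so these calls did not rest on unequal depth. The design text gives separate collection days, but the labels give no collection time, so the explanation stays open. It stays open too for clock genes and lists called with compounds. Differing from both DMSO sets does not exclude collection at another time.

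Other splits of the same samples were drawn for each comparison, the real split included. For a compound, 100 splits of its libraries and the DMSO libraries were fitted. Only the real split (1 of 100) reached the count for retene (152 genes, highest other 10), 4H-cyclopenta(def)phenanthren-4-one (116 genes, highest other 18), carbazole (115 genes, highest other 25), 9-methylanthracene (314 genes, highest other 17), benzo[j]fluoranthene (89 genes, highest other 3), benzo[k]fluoranthene (101 genes, highest other 1), dibenzo[a,h]pyrene (127 genes, highest other 2), dibenzo[a,i]pyrene (28 genes, highest other 0) and benzo[b]fluoranthene (36 genes, highest other 0), which argues against chance for these. For fluoranthene 2 of 100 splits had as many (10, highest other 12) and for phenanthrene 2 (1, highest other 1), and for acenaphthene 3 (1, highest other 1). For 3-nitrofluoranthene 3 of 100 (1, highest other 24) and for 2-methylnaphthalene 2 (1, highest other 14) had as many. These 5 shares were under 0.05, but 4 of them rest on 1 gene. The 3-nitrofluoranthene and 2-methylnaphthalene calls were lost without any 1 of the compound's libraries and the acenaphthene call without replicate 4, so the shares are not taken as excluding chance for these 3. For fluoranthene another split called more genes, and for phenanthrene another called as many. Their shares, not corrected for the number of compounds, do not exclude chance either. For 1,5-dimethylnaphthalene and anthracene, with 0 genes, all 100 had as many, as any split must, so the splits say nothing there (highest other 13 and 14). Splits other than the real one called up to 24 genes for 3-nitrofluoranthene and 25 for carbazole, so regrouped libraries can give calls. The reason was not tested. Of 35 splits, only the real one (1 of 35) reached the count for DMSO_2 against DMSO_1 (21, highest other 1), 9-methylanthracene against anthracene (19, highest other 0), 3-nitrofluoranthene against fluoranthene (1, highest other 0), benzo[b]fluoranthene against benzo[j]fluoranthene (2, highest other 0) and phenanthrene against anthracene (1, highest other 0). No share below 1 of 35 is possible, and the comparisons were not corrected for their number. These splits therefore argue against chance without excluding it, and some comparisons rest on 1 or 2 genes alone. For 1,5-dimethylnaphthalene against 2-methylnaphthalene all 35 had 0 genes, which decides nothing.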

How the results depend on the processing

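Counts of genes moved by over 1.5 times under the settings below, and leaving out the filter moved none. The cause was not tested unless stated. The pseudocount of 1, voom, the library axis and the fit without the 4 deviating libraries were chosen after seeing the data. Against DMSO_1 alone, which drops the requirement that both sets differ, counts of changed genes came to 345 for retene, 618 for 4H-cyclopenta(def)phenanthren-4-one, 596 for carbazole, 358 for 3-nitrofluoranthene, 16 for 1,5-dimethylnaphthalene, 1385 for 9-methylanthracene, 38 for 2-methylnaphthalene, 400 for anthracene, 274 for benzo[j]fluoranthene, 157 for benzo[k]fluoranthene, 467 for dibenzo[a,h]pyrene, 60 for benzo[b]fluoranthene, 48 for fluoranthene, 2 for phenanthrene and 484 for acenaphthene. With DMSO_2 alone they came to 284 for retene, 290 for 4H-cyclopenta(def)phenanthren-4-one, 287 for carbazole, 693 for 9-methylanthracene, 2 for 2-methylnaphthalene, 1 for anthracene, 171 for benzo[j]fluoranthene, 186 for benzo[k]fluoranthene, 773 for dibenzo[a,h]pyrene, 105 for dibenzo[a,i]pyrene, 349 for benzo[b]fluoranthene, 38 for fluoranthene, 19 for phenanthrene and 93 for acenaphthene. The mean of both DMSO sets gave 410 for retene, 731 for 4H-cyclopenta(def)phenanthren-4-one, 711 for carbazole, 101 for 3-nitrofluoranthene, 2 for 1,5-dimethylnaphthalene, 1589 for 9-methylanthracene, 6 for 2-methylnaphthalene, 49 for anthracene, 301 for benzo[j]fluoranthene, 206 for benzo[k]fluoranthene, 1144 for dibenzo[a,h]pyrene, 76 for dibenzo[a,i]pyrene, 338 for benzo[b]fluoranthene, 68 for fluoranthene, 4 for phenanthrene and 1088 for acenaphthene. Without the allowance for the DMSO sets pairs gave 1082 for 9-methylanthracene minus anthracene, 91 for 3-nitrofluoranthene minus fluoranthene, 26 for benzo[b]fluoranthene minus benzo[j]fluoranthene and 85 for phenanthrene minus anthracene. Fitting only a compound and DMSO gave 213 for 4H-cyclopenta(def)phenanthren-4-one, 138 for benzo[j]fluoranthene, 302 for dibenzo[a,h]pyrene, 145 for benzo[b]fluoranthene and 0 for acenaphthene. Without the 4 deviating libraries, which left fewer samples, there were 256 for 4H-cyclopenta(def)phenanthren-4-one, 251 for carbazole, 2 for 3-nitrofluoranthene, 730 for 9-methylanthracene, 407 for dibenzo[a,h]pyrene, 159 for benzo[b]fluoranthene, 0 for acenaphthene, 40 for DMSO_2 minus DMSO_1 and 43 for 9-methylanthracene minus anthracene. Quantile normalization gave 6 for fluoranthene. With the replicate number as a block there were 0 for 3-nitrofluoranthene and 6 for fluoranthene. Voom gave 69 for dibenzo[a,h]pyrene, 5 for fluoranthene and 1 for benzo[b]fluoranthene minus benzo[j]fluoranthene. A pseudocount of 8 gave 0 for benzo[b]fluoranthene minus benzo[j]fluoranthene. A pseudocount of 1 gave 1 for anthracene and 0 for benzo[b]fluoranthene minus benzo[j]fluoranthene. In the fits made to test explanations, the library axis as a covariate gave 2 for 2-methylnaphthalene, 0 for acenaphthene, 32 for 9-methylanthracene minus anthracene and 4 for benzo[b]fluoranthene minus benzo[j]fluoranthene, and thinning gave 0 for 2-methylnaphthalene. The 53 called compound and list combinations became 21 with an estimated correlation, 103 with the mean control and 55 with quantile normalization. Leaving out each library in turn, which also leaves fewer samples, gave ranges of 27 to 101 for 4H-cyclopenta(def)phenanthren-4-one, 45 to 128 for carbazole, 0 to 2 for 3-nitrofluoranthene, 125 to 293 for 9-methylanthracene, 0 to 1 for 2-methylnaphthalene, 0 to 1 for anthracene, 58 to 78 for benzo[j]fluoranthene, 47 to 157 for dibenzo[a,h]pyrene, 5 to 8 for fluoranthene, 0 to 7 for acenaphthene, 11 to 21 for DMSO_2 minus DMSO_1, 10 to 24 for 9-methylanthracene minus anthracene, 1 to 2 for benzo[b]fluoranthene minus benzo[j]fluoranthene and 1 to 2 for phenanthrene minus anthracene. It moved no count that far for the rest: 118 to 138 for retene, 0 throughout for 1,5-dimethylnaphthalene, 82 to 96 for benzo[k]fluoranthene, 24 to 28 for dibenzo[a,i]pyrene, 29 to 38 for benzo[b]fluoranthene, 1 throughout for phenanthrene, 1 throughout for 3-nitrofluoranthene minus fluoranthene and 0 throughout for 1,5-dimethylnaphthalene minus 2-methylnaphthalene. Of 525 named gene results, 255 of them called, quantile normalization ended 13 calls, voom 23 and the block 15. Apart from klf2b, calls ended by the block are not named gene by gene. There were 4 calls lost with a pseudocount of 8 and 2 with no filter. The pseudocount of 8 added 2 calls and the block 2, and no direction of a called gene turned. The replicate numbers did not pair the samples: deviations of same-numbered libraries of different groups correlated at a mean of 0.0046 against -0.0007 for other numbers over genes, 12 of 72 libraries correlated best with their own number, and the block therefore shares only a number. The edgeR and DESeq2 fits planned for raw counts were not run. The deposited values are on a log2 scale, and voom on the recovered reads took the place of those fits. Depth limits the weakest genes: a count of 0 allows up to 3 reads, which is 1.63 to 4.18 normalized counts by library, for counting error only.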

Other observations

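The genes named here were chosen after their values were seen, and none of these recurrences was tested. Of 685 genes called with any compound, 19 were higher with 5 or more compounds, 43 lower with 3 or more and 2 called in both directions. SIK1, a salt-inducible kinase gene, was lower with 6 compounds: 9-methylanthracene, dibenzo[a,h]pyrene, dibenzo[a,i]pyrene, benzo[b]fluoranthene, fluoranthene and phenanthrene, by log2 differences of -0.88 to -0.52. RGS2, a regulator of G protein signalling, was lower with 6 (-0.50 to -0.41) and si:dkey-65b12.6 with 6 (-1.11 to -0.69). The mucin gene muc5.1 was lower with 4 compounds (-1.12 to -0.71).

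These genes, not among the matched members of the fixed lists, were also picked after their values were seen. Each was lower with 9-methylanthracene, 4H-cyclopenta(def)phenanthren-4-one and carbazole, and no gene group was tested from them. They were RCVRN (ENSDARG00000019902), recoverin (log2 differences of -0.61 to -0.51), PROM1 (ENSDARG00000034007, -0.81 to -0.65), ABCA4 (ENSDARG00000062661), a photoreceptor transporter (-0.56 to -0.41), rpgrip1 (-0.45 to -0.39) and the retinoschisin gene rs1a (-0.60 to -0.57). The muscle gene AMPD1 was lower with the same 3 compounds (-0.65 to -0.51). These genes had normalized count means in DMSO of 393 (RCVRN), 382 (PROM1), 78.1 (ABCA4) and 3976 (AMPD1). The fixed photoreceptor list named rcvrn2 and rcvrn3, which matched no symbol, so RCVRN may stand for a listed gene.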
